A study of Pomacea canaliculata with 12 samples.

How the data were processed

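Poly(A) RNA was extracted with Trizol from 4 tissues of Pomacea canaliculata, a freshwater apple snail with a camera-type eye, per the labels' protocols. The tissues were extracted retina, eye stalk, cephalic tentacle and oral tentacle, with 3 libraries each. The authors deposited 1 table of whole-number read counts per gene, not normalized, with 21131 genes and 12 libraries. The unit was read from the values, because library totals differ and hold no fractions. Reads were aligned with STAR, per the submitters' processing notes. The STAR version, the counting tool, its strand setting, the genome build and the annotation release are not given in the sources used here. Every count column carried the title of exactly 1 sample, and each title placed its library in a tissue with a replicate number. The labels do not say whether libraries of one tissue came from different animals, nor whether libraries pool animals. The p-values therefore measure only the spread between these libraries, which may be partly technical.

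Genes were named in the table by LOC identifiers only. All 21131 identifiers were found in the reference gene table of assembly ASM307304v1, all as protein-coding genes, and 0 of them had a symbol other than the identifier. No product description could be paired with any gene. The 23 gene lists fixed before the data were examined were defined on product descriptions, so their set tests were not run and no gene is given a function here. Because the build behind the counts is unknown, no coordinates or gene lengths are reported, and the reference table was used only to tell which genes neighbour each other.

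Library totals ran from 10804847 to 45673871 counts. The retina libraries held at least 40794864 and the other 9 libraries at most 21561988, so depth and tissue were confounded for the retina. A total of 0 counts over a tissue's libraries allows up to 3 counts. Folds against that floor, and the Poisson 95% intervals given for ratios against 1 to 3 counts, cover counting error only.

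The main test was edgeR 4.0.16 (R 4.3.3) with quasi-likelihood F-tests (glmQLFit and glmQLFTest, robust) on the deposited counts. Genes were filtered with filterByExpr at its default minimum count of 10, which left 16811 genes, and libraries were scaled with TMM factors. All 12 libraries entered 1 fit with tissue as the only term, giving 8 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the F statistic. The tentacle reference is the mean of the cephalic and oral tentacle coefficients. Normalised CPM were computed from the deposited counts and TMM-scaled library sizes, and values with ± are means and SDs over libraries. A fold against a side of a comparison with 0 counts is a lower bound, computed against 3 counts over all libraries of that side. Medians and 32-fold counts of fitted changes are given also with such genes at their bound.

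The naming rule fixed before the data were examined required a product description, which no gene had. Its first part was kept without that requirement and shortened to 2 genes in each direction per comparison. These are the called genes with the largest log2 fold changes, a mean logCPM of at least 1 and no overlap of normalised CPM between the libraries compared. All 14 genes named here were therefore chosen outside the rule as it was written, and the rule was relaxed after the data were seen.

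Presence was scored after every library was thinned at random to 10804847 counts, the total of the shallowest, and again with every library thinned to one TMM-scaled size. A gene was present in a tissue with at least 10 counts in all 3 libraries and near-absent with at most 3 counts in each. Overlap between comparisons that share the tentacle libraries was set beside 20 simulations of unchanged retina and eye stalk libraries, the overlap of independent lists, and splits of the tentacle libraries by tissue and by replicate number. No 2 libraries of a tissue agreed within sampling noise: the chi-square over genes with at least 20 counts in the pair ran from 34.02 to 665.9 per degree of freedom.

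Replicate numbers come from the titles. Retina carries 1, 3 and 4 and the other tissues 1, 2 and 3. Deviations from the tissue means were correlated between same-numbered cephalic and oral tentacle libraries (r = 0.38, 0.29 and 0.53 for numbers 1, 2 and 3, across genes), so these numbers were taken to pair the tentacle libraries. Same-numbered eye stalk and cephalic tentacle libraries had r = -0.32, 0.03 and -0.38, and retina shares only 2 numbers with the other tissues, so no other pairing was taken as shown. The replicate block over all 12 libraries nevertheless treats equal numbers as shared by all 4 tissues. Calls lost under this block outside the tentacle comparison rest on that. The main fit and the SDs over all tentacle libraries treat same-numbered tentacle libraries as separate. Its p-values for retina or eye stalk against the tentacles may therefore be too small.

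The edgeR code was tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 of 16811 genes changed. For retina against eye stalk it recovered 12% of 2-fold, 56% of 4-fold, 72% of 8-fold and 80% of 16-fold changes, with 4 false calls. The real comparison of retina with eye stalk called 54.9% of genes. Adjustment is less strict where more genes change, so these shares do not measure recovery in that comparison. For cephalic against oral tentacle the shares were 18%, 56%, 72% and 78%, with 5 false calls. Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, only the compared tissues in the fit, a replicate block, scaling without the 50 most abundant genes, a minimum log2 fold change of 1, and leaving out each library. Alternatives chosen after seeing the data were equal depth, a block within the tentacle libraries, leaving out pairs of libraries that stood apart, the split of the tentacle libraries by replicate number, and other thresholds and thinnings for the strongly retina-biased and presence sets.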

Results

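Transcript levels were compared between the eye and the neighbouring sensory appendages of the snail head. The 12 poly(A) RNA libraries covered retina, eye stalk, cephalic tentacle and oral tentacle, each with 3 libraries, and 16811 of 21131 protein-coding genes had enough counts to be tested. Retina replicates 1, 3 and 4 held 40794864, 41677121 and 45673871 counts. Replicates 1, 2 and 3 held 12286896, 11890390 and 11951786 counts in eye stalk, 21561988, 12128796 and 16825005 in cephalic tentacle, and 17161875, 10804847 and 11426763 in oral tentacle. Whether the eye stalk samples included the eye is not stated in the labels. Genes carry LOC identifiers only, so the tissues are described by how many genes differed and by how much, with few single genes.

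The retina stood apart from the 3 other tissues, and the 2 tentacle types were close to each other. The first principal component of log2 CPM held 56.5% of the variance and separated the retina libraries (scores 170.2 to 208.2) from the other 9 (-98.1 to -20.5). The second held 15.8% and separated the eye stalk (-117.3 to -89.7) from the tentacles (30.1 to 52.3). Across genes, log2 CPM correlated with a mean r of 0.95 between retina libraries, 0.79 between retina and eye stalk, and 0.74 and 0.73 between retina and cephalic or oral tentacle. Cephalic and oral tentacle libraries had a mean r of 0.91, against 0.92 within each of these tissues. Genes are not independent replicates, so these r values describe similarity only.

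**Figure D1:**
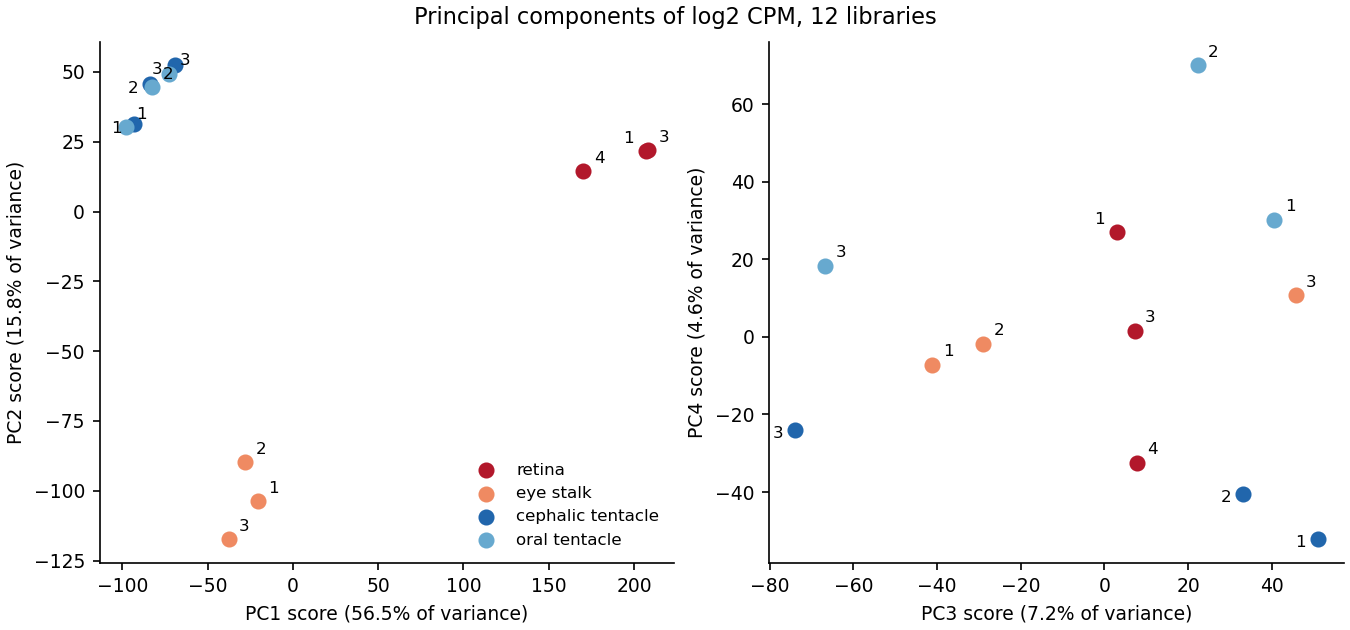
Scores of the 12 libraries on principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM over 16811 genes, coloured by tissue and labelled by replicate number. The retina lies alone at the right of component 1 and the eye stalk alone at the bottom of component 2, while component 3 places the cephalic and oral tentacle libraries numbered 3 together at -73.9 and -66.8, apart from those numbered 1 and 2.

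Fewer genes were detected in retina than in the other tissues. At equal total counts, 13329 ± 182 genes (SD, n = 3) reached 10 counts in retina, against 15507 ± 76.9 in eye stalk, 15526 ± 78.2 in cephalic tentacle and 15573 ± 66.0 in oral tentacle. All 3 retina libraries lay below the other 9 (exact permutation test, two-sided, p = 0.0045, the smallest that 220 splits allow). This test, here and at scaled size below, treats same-numbered tentacle libraries as separate although they were correlated, so its p may be too small. The TMM factors were 0.71 to 0.77 in retina and 1.01 to 1.15 elsewhere. At equal TMM-scaled library size, 13895 ± 208 genes reached 10 counts in retina, 15535 ± 101 in eye stalk, 15470.33 ± 58.0 in cephalic tentacle and 15546 ± 42.4 in oral tentacle, and all 3 retina libraries again lay below the other 9 (exact permutation test, two-sided, p = 0.0045). By the presence rule at equal total counts, 11729 genes were present in all 4 tissues. Among genes that separated tissues cleanly, 294 were present in eye stalk and both tentacles but near-absent from retina. A further 55 were present in both tentacles only, 21 in retina and eye stalk only, 15 in oral tentacle only, 4 in retina only, 4 in eye stalk only and 1 in cephalic tentacle only. These sizes depend on the thresholds: with 20 counts for presence, 152 genes were missing from retina alone and 2 were present in retina only, and with 0 counts for absence these numbers were 66 and 0. With the main thresholds at equal TMM-scaled library size they were 201 and 11.

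Retina was first compared with the tentacles, the sensory appendages without a retina. Of the genes tested, 5425 were higher in retina and 5454 higher in the tentacles, together 64.7% (edgeR quasi-likelihood test, adjusted p under 0.05). Genes higher in retina had a median log2 fold change of 1.03, and genes lower in retina had a median size of 2.82, unchanged to 2 decimals when the 407 of them with 0 counts in retina were set to their bounds. At least 32-fold differences were fitted for 192 genes higher and 1034 genes lower in retina, and 870 of the lower set reached 32-fold with those genes at their bounds. LOC112573779 had 845 ± 491 CPM in retina (SD, n = 3) and a total of 1 count over the 6 tentacle libraries, a ratio of 85599.5 (Poisson 95% interval 15363 to 3381000; edgeR adjusted p = 3.0e-07). Without retina replicate 4 this ratio was 56900.3 (10212.5 to 2247440). LOC112562530 was the most abundant transcript of retina replicate 4. It had 4439, 6609.61 and 130760 CPM in retina replicates 1, 3 and 4 and 1.39 ± 0.71 CPM in the tentacles (n = 6), a log2 fold change of 15.05 ± 1.36 (SE, edgeR adjusted p = 6.7e-06). Without retina replicate 4 its log2 fold change was 11.95.

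In the other direction, LOC112572453 had 50.2 ± 16.9 CPM in the tentacles (SD, n = 6) and 0 counts in retina, at least 1599-fold lower (edgeR adjusted p = 2.3e-05). LOC112567912 also had 0 counts in retina, but its level elsewhere was uneven. It had 473 CPM in cephalic tentacle replicate 1, 401 in oral tentacle replicate 1 and 735 in eye stalk replicate 3, and 0.60 to 6.53 CPM in the other 6 libraries. Its call (edgeR adjusted p = 0.046) held in 10 of 20 alternatives (edgeR adjusted p from 0.032 to 0.096). It was lost without cephalic tentacle replicate 1 (0.076), oral tentacle replicate 1 (0.072), eye stalk replicate 2 (0.0501) or retina replicate 1, 3 or 4 (0.094, 0.096 and 0.095), with a replicate block (0.061), without a low-count filter (0.056), with equal total counts (0.070), and without both retina replicate 4 and eye stalk replicate 3 (0.076). RLE scaling lowered the median log2 fold change of all genes from -0.04 to -0.17 and the share of calls that were higher in retina from 49.9% to 44.6%. DESeq2 called 4981 genes higher and 6757 lower in retina, and edgeR without a low-count filter 5093 and 6201.

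**Figure D2:**
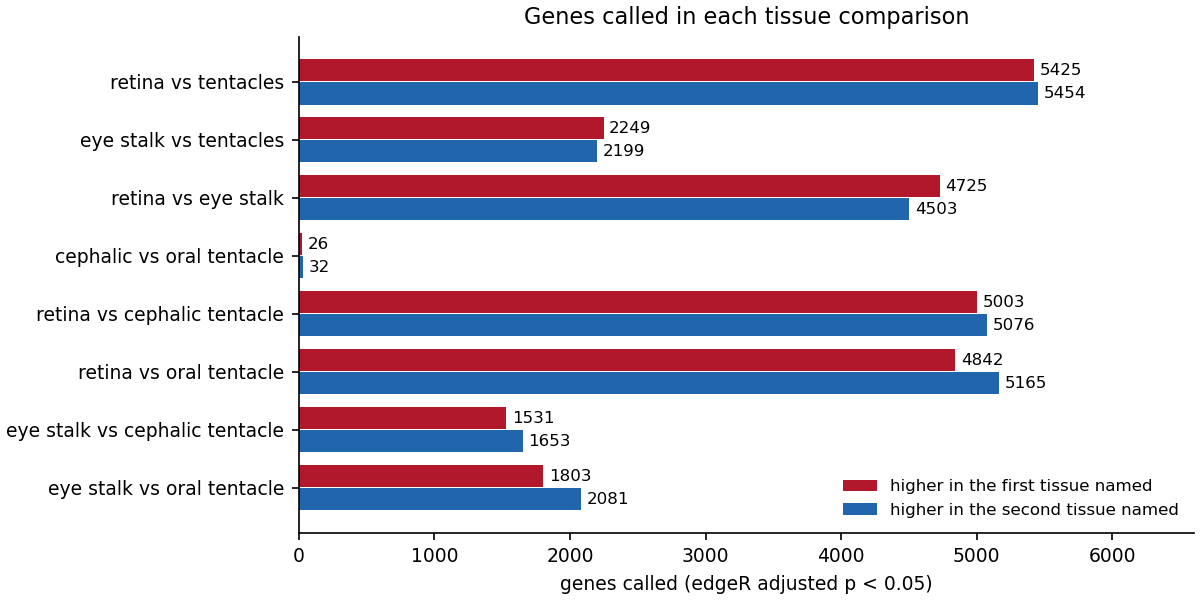
Number of genes called at an edgeR adjusted p under 0.05 in each comparison (horizontal axis), with red bars for genes higher in the first tissue named and blue bars for genes higher in the second. Comparisons with retina called 9228 to 10879 genes, those of eye stalk with tentacles 3184 to 4448, and cephalic against oral tentacle 58.

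The eye stalk differed from the tentacles in fewer genes. It had 2249 genes higher and 2199 lower than the tentacle mean, 26.5% of those tested, with median log2 sizes of 1.02 and 1.39 (edgeR quasi-likelihood test, adjusted p under 0.05). Among genes meeting the naming rule, LOC112573779 had the largest fitted log2 fold change between retina and tentacles, and also led here. It had 306 ± 85.4 CPM in eye stalk (SD, n = 3), a ratio of 31031.5 to the 1 count in the tentacles (Poisson 95% interval 5569.53 to 1225680; edgeR adjusted p = 2.8e-06). LOC112558777 had 92.9 ± 7.74 CPM in eye stalk and 1 count in the tentacles, a ratio of 9419 (interval 1690.44 to 372011; edgeR adjusted p = 2.7e-07). LOC112576325 and LOC112554686 had 0 counts in all eye stalk libraries and 12.7 ± 15.9 and 7.09 ± 3.04 CPM in the tentacles (n = 6), at least 161-fold and 90.5-fold lower (edgeR adjusted p = 0.0099 and 0.00065). Oral tentacle replicate 3 held 44.0 CPM of LOC112576325, and without it the bound was 81.4-fold. Set against each tentacle type alone, eye stalk had 1531 genes higher and 1653 lower than cephalic tentacle, and 1803 higher and 2081 lower than oral tentacle. Without eye stalk replicate 1 the counts against oral tentacle were 1195 and 1359, and without cephalic tentacle replicate 2 the number higher in eye stalk than cephalic tentacle was 837. That number was 1017 without eye stalk replicate 1 and 998 without cephalic tentacle replicate 1, and 1377 genes were lower than in oral tentacle without oral tentacle replicate 2.

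Retina and eye stalk shared many of their differences from the tentacles. Of the 2249 genes higher in eye stalk, 1430 (63.6%) were also higher in retina, against 726 for independent lists. Of the 2199 genes lower in eye stalk, 1315 were also lower in retina, against 713 for independent lists. In 20 simulations with unchanged retina and eye stalk at most 2 genes were higher in both and 0 lower in both, which gives chance with no effect and no reference for lists of this length. Opposite calls were made for 277 genes higher in retina and lower in eye stalk and for 345 lower in retina and higher in eye stalk. Because both comparisons use the same tentacle libraries, the overlap was counted again with the controls split. Retina against cephalic and eye stalk against oral tentacle shared 1111 higher genes (537 for independent lists), and the reverse split shared 954 (441). Same-numbered cephalic and oral libraries deviated together, so these controls were not independent. With same-numbered tentacle libraries kept on the same side, the 6 splits shared 732 to 1149 higher genes and 734 to 1104 lower genes. These were 1.82 to 2.42 times and 1.82 to 2.28 times the numbers for independent lists. Every split still had tentacle tissue as the reference, so a gene particular to the tentacles enters both lists. The number for independent lists also takes every gene as equally likely to be called. The excess therefore does not show a programme shared by retina and eye stalk.

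Genes far higher in retina than in the tentacles were mostly called higher in eye stalk than in the tentacles as well. In all, 163 genes were called and fitted as at least 32-fold higher in retina than in the tentacles with at least 5 CPM in retina, and 150 of them were also called higher in eye stalk than in the tentacles, 0 were called lower and 13 were not called. Their median level in the eye stalk libraries was 20.7%, 24.3% and 14.7% of the retina mean in replicates 1, 2 and 3 (mean 19.9 ± 4.81%, SD, n = 3). In cephalic and oral tentacle it was 1.01 ± 0.07% and 0.98 ± 0.17%, levels kept low by the selection, and the calls in eye stalk rest on the same tentacle libraries. These genes took 15.4 ± 5.87% of the counts in retina, 4.09 ± 1.13% in eye stalk and 0.12% in each tentacle type (SD under 0.02, n = 3 each). Of the 163 genes, 139 were called higher in retina than in eye stalk, 0 lower, and 4 had at most 3 counts in every eye stalk library.

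**Figure D3:**
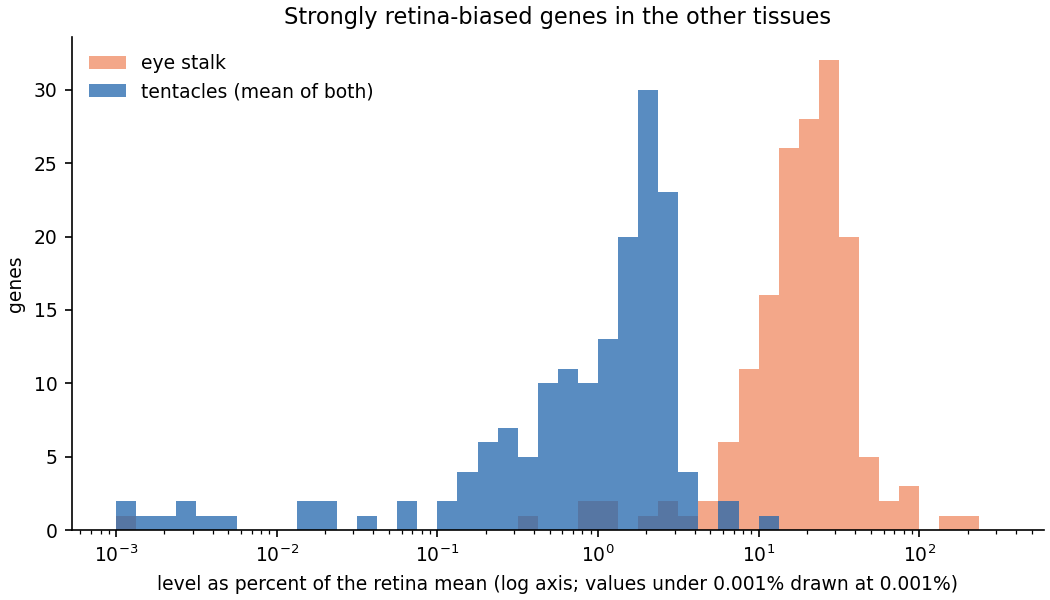
Level of the 163 strongly retina-biased genes in eye stalk and in the tentacles, as a percent of each gene's retina mean (horizontal log axis), with the number of genes on the vertical axis. The library medians average 19.9% in eye stalk, 1.01% in cephalic tentacle and 0.98% in oral tentacle, and both the eye stalk and the tentacle values extend to 0.

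The direct comparison of retina with eye stalk called 4725 genes higher in retina and 4503 higher in eye stalk, 54.9% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05). Which direction had more calls depended on the processing: the numbers were 4131 and 4846 with RLE scaling, which lowered the median log2 fold change of all genes from 0.04 to -0.07, 4394 and 5540 with DESeq2, and 4239 and 5076 without a low-count filter. Genes higher in retina had a median log2 fold change of 1.07 and genes lower had a median size of 3.02, or 2.96 with the 306 genes at 0 counts in retina set to their bounds. For at least 32-fold differences, 22 genes were fitted as higher in retina and 900 as higher in eye stalk, or 19 and 779 with genes at 0 counts at their bounds. LOC112556666 had 7.07 ± 1.79 CPM in retina (SD, n = 3) and 0 counts in eye stalk, at least 90.2-fold higher (edgeR adjusted p = 0.0052). LOC112561182 had 8.48 ± 0.88 CPM in retina and 1 count in eye stalk, a ratio of 325 (Poisson 95% interval 58.2 to 12817.5; edgeR adjusted p = 0.00030). LOC112564707 had 0 counts in retina and 33.5, 22.9 and 1201 CPM in eye stalk replicates 1, 2 and 3, at least 13354-fold higher in eye stalk (edgeR adjusted p = 0.0014), and without replicate 3 it stayed called at a bound of 898-fold (edgeR adjusted p = 0.00018). LOC112567912 was again lower in retina (edgeR adjusted p = 0.047), and this call held in 9 of 19 alternatives (adjusted p from 0.028 to 0.30 with edgeR). It was lost without eye stalk replicate 3 (adjusted p = 0.19), without eye stalk replicate 1 or 2 (0.051 and 0.052), without oral tentacle replicate 3 (0.053), without any 1 retina library (0.095 to 0.098), without a low-count filter (0.059), with equal total counts (0.070), and without both retina replicate 4 and eye stalk replicate 3 (0.30).

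Genes higher in retina than in each of the 3 other tissues numbered 3394, of which 1570 were at least 2-fold higher than in every one. The 3394 genes took 60.2 ± 2.16% of the counts in retina, 31.1 ± 2.47% in eye stalk, 25.6 ± 0.24% in cephalic tentacle and 25.9 ± 0.89% in oral tentacle (SD, n = 3 each). They were selected on these libraries, so the shares describe the set and are not independent evidence of its direction. Against single tentacle types, retina had 5003 genes higher and 5076 lower than cephalic tentacle, and 4842 higher and 5165 lower than oral tentacle.

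**Figure D4:**
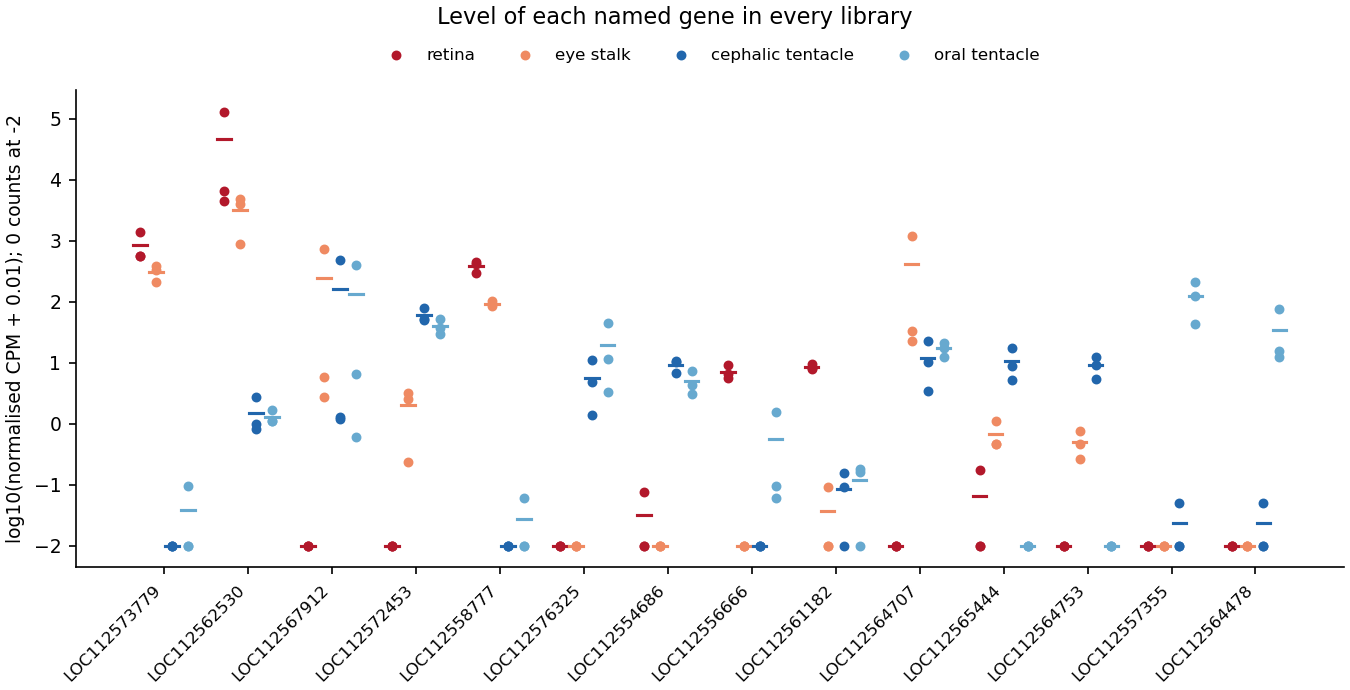
Normalised CPM of the 14 named genes in each of the 12 libraries, on a log10 scale after adding 0.01 CPM, so that 0 counts lie at -2. Points are libraries, coloured by tissue, and bars are tissue means (n = 3). LOC112562530 and LOC112564707 each have 1 library far above the others of a tissue, in retina and eye stalk respectively, and LOC112567912 has 1 such library in eye stalk and in each tentacle.

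Cephalic and oral tentacle differed in few genes. The fit called 26 genes higher in cephalic and 32 higher in oral tentacle, 0.35% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05), with median log2 sizes of 3.10 and 4.48. LOC112565444 and LOC112564753 had 10.5 ± 6.17 and 8.99 ± 3.36 CPM in cephalic tentacle (SD, n = 3) and 0 counts in oral tentacle, at least 154-fold and 132-fold higher (edgeR adjusted p = 0.048 and 0.016). LOC112557355 and LOC112564478 had 126 ± 83.4 and 34.7 ± 36.3 CPM in oral tentacle and 1 count each in cephalic tentacle. The ratios were 7198 (Poisson 95% interval 1292 to 284323) and 1984 (356 to 78359.6), with edgeR adjusted p = 0.0080 and 0.040. Without oral replicate 2 the first ratio was 4795.5 (860.698 to 189412), and without oral replicate 3 the second was 787 (141 to 31066). Neither of these 2 genes had a count in retina or eye stalk.

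The cephalic and oral libraries with the same number deviated together, so a replicate block was also fitted. Over all 12 libraries it called 16 genes higher in cephalic and 23 higher in oral tentacle, and LOC112565444, LOC112564753 and LOC112564478 were then not called (edgeR adjusted p = 0.10, 0.069 and 0.066). In the 6 tentacle libraries alone it called 9 and 14 genes, and LOC112565444 and LOC112564753 were not called (edgeR adjusted p = 0.095 and 0.10). DESeq2 called 194 and 176 genes, among them all 58 of the edgeR calls. Single libraries moved these counts. Genes higher in cephalic and in oral tentacle numbered 14 and 9, 13 and 11, and 16 and 15 without cephalic replicate 1, 2 or 3, and 14 and 24, 13 and 14, and 18 and 27 without oral replicate 1, 2 or 3. They numbered 40 and 43 without retina replicate 4, and 5 and 4 without both tentacle libraries numbered 3. Over 21 alternatives LOC112565444 was called in 7 (adjusted p with edgeR or DESeq2 from 9.2e-09 to 0.20), LOC112564753 in 14 (5.3e-10 to 0.10), LOC112557355 in 17 (1.1e-17 to 0.13) and LOC112564478 in 13 (0.0023 to 0.27). LOC112565444 was lost without any 1 tentacle or eye stalk library or retina replicate 3. LOC112564753 was lost without cephalic replicate 1 or 2 or oral replicate 2 (0.083, 0.091 and 0.053), LOC112557355 without cephalic replicate 1, 2 or 3 (0.11, 0.064 and 0.053), and LOC112564478 without any 1 cephalic library (0.15 to 0.27) or oral replicate 1 or 2 (0.053 and 0.090). In simulated counts with 200 changed genes, 18% of 2-fold and 56% of 4-fold changes between these tissues were recovered.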

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

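The equal depth, the block within the tentacle libraries, the omission of 2 libraries together, the retina level from replicates 1 and 3, the other thresholds and thinnings of the presence and retina-biased sets and a split of the tentacle controls by replicate number were chosen after seeing the data. Among genes called both with the stated settings and with an alternative, 0 changed sign. With every library thinned to the shallowest total, 10137 of the 10879 calls between retina and tentacles were kept, so a greater retina total does not account for those 10137. Counts of calls stayed within 1.5 times of the main counts for every comparison under RLE scaling, no low-count filter, scaling without the 50 most abundant genes and equal depth. A replicate block over all libraries moved 1 count by over 1.5 times, that of genes higher in cephalic than oral tentacle (16 with the replicate block, 26 without it). Of the named genes it ended the calls of LOC112567912 against the tentacles and of LOC112565444, LOC112564753 and LOC112564478 between the tentacles, and no other. A minimum log2 fold change of 1 by construction keeps fewer genes. It left 2844 genes higher and 4759 lower in retina than tentacles, and 2625 higher and 3936 lower in retina than eye stalk. Against cephalic tentacle, 2774 genes were then higher and 4567 lower in retina, and against oral tentacle 2724 and 4579. At this minimum more genes were thus lower than higher in retina. Eye stalk had 1140 genes higher and 1465 lower than the tentacles, 886 and 1306 against cephalic, and 988 and 1444 against oral tentacle. This minimum left 1570 retina-enriched genes and 588 higher in both retina and eye stalk. The cephalic against oral comparison moved most: 194 and 176 genes with DESeq2, 15 higher in oral tentacle with only the tentacle tissues fitted, 9 and 14 with the tentacle libraries alone and the replicate block, and 5 and 4 without both replicates 3. DESeq2 gave no adjusted p for LOC112562530 and LOC112567912 between retina and tentacles, nor for LOC112564707 and LOC112567912 between retina and eye stalk. The cause of the difference between the tools was not tested. Leaving out 1 library at a time gave 13 to 40 genes higher in cephalic and 9 to 43 higher in oral tentacle, with both maxima without retina replicate 4. It gave 837 to 1900 genes higher in eye stalk than cephalic tentacle, 1195 to 2181 higher and 1359 to 2471 lower in eye stalk than oral tentacle, 1512 to 2702 higher and 1475 to 2582 lower in eye stalk than the tentacles, and 972 to 1610 higher in both eye tissues. The mean of the library medians of the retina-biased genes in eye stalk, 19.9%, was 21.7% against retina replicates 1 and 3 alone. The gene list tests and their alternatives were not run, because no gene could be paired with a product description.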

Other observations

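The tests of the source of LOC112562530, of raised genes within other tissues' levels, of the 6 pairings, of leakage between libraries, of abundant genes in retina replicate 4 and of splits that keep paired libraries together were chosen after the results were seen. In the gene order of assembly ASM307304v1, 2 of 3 gene sets tested, both defined by the retina, held more neighbours than random sets. The 1570 genes at least 2-fold higher in retina than in each other tissue formed 242 adjacent pairs among the 16811 tested genes, against a mean of 146 and a highest of 184 in 10000 random sets (one-sided permutation test, p = 1e-04, the smallest these sets can give, adjusted p = 0.00015 over 3 sets), with a longest run of 5 genes. The 294 genes present, at equal total counts, in every tissue but retina formed 28 adjacent pairs, against a mean of 5.35 and a highest of 15 in random sets drawn from 13659 genes present in the other tissues (one-sided permutation test, p = 1e-04, adjusted p = 0.00015). The 58 genes called between cephalic and oral tentacle formed 0 pairs, against a mean of 0.19 (one-sided permutation test, p = 1). With so few pairs expected, the test of these 58 genes could hardly show clustering or its lack. It gives no contrast to the 2 retina sets. In those 2 sets, neighbouring genes may share a bias to the retina or a lack of expression in it. Tandem copies that share reads would also give adjacent pairs, and this was not tested.

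Other splits of the compared libraries were fitted with 2 groups. For retina against tentacles the real split gave 10552 calls and the other splits of 84 at most 10, and for eye stalk against tentacles it gave 4891 and the others at most 18. Every other split put retina or eye stalk libraries in a group with tentacle libraries. Where tissues differ this widens the spread within groups, so the few calls in other splits are weak evidence. The 84 splits also treat the tentacle libraries as single, although same-numbered ones were correlated. With these pairs kept together 10 splits remain, too few for a share under 0.05, and the others gave at most 0 calls for retina and 8 for eye stalk. For retina against eye stalk (7455 calls, at most 0 in the others) and cephalic against oral tentacle (34, at most 2) the real split was also 1 of 10, too few for a share under 0.05. Among the 4 splits that part all 3 pairs of tentacle libraries, the fit with a replicate block gave 23 calls for the real split and at most 0 for the others.

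Retina replicate 4 had 107 genes raised at least 8-fold over the mean of the other retina libraries, against 10 and 2 in replicates 1 and 3, although cephalic tentacle replicate 3 also had 107. Eye stalk or tentacle tissue as the source of LOC112562530 is argued against by its level, 26.9 times the highest in any library of another tissue. For the other raised genes, eye stalk tissue was gauged by 38 genes abundant outside the retina. These reached a median of 1.81% of the eye stalk level where 337% was needed (ratio 0.0054, bootstrap 95% interval 0.0032 to 0.015). This interval and the next resample genes within this 1 library and hold no spread between libraries. No share of eye stalk tissue can meet a need above the whole eye stalk level, so the ratio was bound to be low and adds no separate support. Of the 107 raised genes, 61 lay above every library of the other tissues, which argues against those tissues as their source. The share of counts outside each library's 50 most abundant genes was 0.896 and 0.903 of that in the other retina libraries, where an 8-fold difference was needed for a few abundant genes to be the cause. A smaller share lowers the other genes and cannot raise them, so this outcome was fixed by the shares and adds no separate support. For the 46 raised genes within other tissues' levels, eye stalk or tentacle tissue as the source is argued against at the median: the 38 genes reached a median of 1.59% of the higher tissue level where 18.8% was needed (ratio 0.084, interval 0.042 to 0.22). The lower quartile of the need was 7.14%, and 2 of the 38 genes exceeded 10%, so such a source is not excluded for part of the 46. A carry-over as small as 1.59% is not excluded. A difference between animals or in dissection was not tested.

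Cephalic and oral tentacle libraries of one number deviated together from their tissue means. A few on-off genes as the whole cause are argued against by a lowest same-number correlation of 0.17 without the 10% of genes that varied most, and a difference in depth by a lowest correlation of 0.30 with all libraries thinned to one total. Equal numbers gave the highest mean correlation of the 6 pairings (0.40, next 0.23, so 1 of 6 as high), which is consistent with a shared animal, day or batch, but 6 pairings are too few to exclude chance and the labels name none of these. Eye stalk numbers did not follow this pairing: eye stalk replicate 3 correlated at 0.42 with cephalic replicate 1 and at -0.38 with cephalic replicate 3, across genes.

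In the eye stalk libraries the median level of the strongly retina-biased transcripts was 14.7% to 24.3% of the retina mean. Eye stalk means of single genes ran from 0 to 220%. Leakage of reads from the deeper retina libraries as the only source would put every gene at or above one share of its lowest retina library. Of 122 genes with at least 20 counts expected at that share in each eye stalk library, 2 (1.64%, exact binomial 95% interval 0.199 to 5.8%) lay under 0.5 of it in all 3, too few to decide. LOC112557531 and LOC112554699 had eye stalk means at 220% and 156% of their retina means, more than such a share gives. Of the 163 genes, however, 0 were called higher in eye stalk than in retina, so neither excess was called. LOC112557531 and LOC112554699 are also single genes: 95% of the 163 genes lay at or under 63.2%, 64.2% and 39.5% in replicates 1, 2 and 3. For the set, leakage cannot be told apart from expression in the eye stalk. A candidate explanation is 1 share of retina tissue in each eye stalk library, which would give all these genes a like percent. The robust SD across genes of log2(eye stalk / retina) was 0.81, 1.03 and 1.08 in replicates 1, 2 and 3, and the smallest was 0.73 of the largest between retina libraries (1.10) but 1.61 times the smallest (0.50). Which retina pair is taken decides the outcome, and the eye stalk ratios use the retina mean where the retina ratios use single libraries. Retina tissue in these samples therefore cannot be told apart from expression by eye stalk cells.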
